A study of Homo sapiens with 6 samples.

How the data were processed

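The series comprised 6 libraries of MDA-MB-231 cells, 3 with a control vector and 3 with a vector for RPPH1 overexpression. Per the labels' protocols, total RNA with an integrity number that passed the submitters' limit was made into stranded mRNA libraries with an Illumina TruSeq kit. Trimmomatic, HISAT2, Cufflinks and the GRCh38 build are named in the submitters' processing notes, without tool versions, and the annotation release was not given in the sources used here. The deposited values were FPKM, that is fragments scaled to gene length and to the fragment total of the library, with 1 column per library and 17088 genes listed. FPKM divides out depth and gene length, so a value alone does not show its counting error, and reads shared between near-identical genes were assigned by the authors' pipeline before the values were made. RPPH1 is transcribed by RNA polymerase III and lacks a poly(A) tail, which mRNA libraries select for, and its own transcript was not analysed here.

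The fragments behind the FPKM values were recovered from the file. Each value is a whole fragment number times a step set by gene length and library total, and 6 totals were found that made every value whole in 10909 of 10909 tested genes (100%), within 0.01 fragments plus a relative 3e-08. The totals were 17603126 to 18817269 fragments, and 99.4% of each fell in the listed genes. On 3881 tested genes of simulated FPKM values, 6 of 6 totals came back within 1 fragment and 98.9% of genes had all fragment numbers exact; the rest were divided by a whole factor. The 10 genes with the highest FPKM held 6.23% to 6.36% of the FPKM sum in each library. Pairs of replicates differed beyond counting noise, with a chi-square per degree of freedom of 2.21 to 8.36. Each library was counted as 1 sample.

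Tests had been designed for counts, with a fallback for FPKM fixed at the same time, and the fallback was used. Genes with at least 1 FPKM in at least 3 libraries were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a mean-variance trend in the empirical Bayes step and group as the only term. A fold change is therefore on the log2(FPKM + 1) scale, which understates changes of genes at low levels. Adjusted p-values are Benjamini-Hochberg values over the 10909 genes, with a threshold of 0.05 and no fold threshold. An exact permutation test of 3 against 3 libraries has 10 splits and a smallest two-sided p of 0.1, so it could not pass the threshold. The design and the alternatives were fixed before the data were examined, except those named below as added.

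In total 28 gene lists were fixed before the data were examined, and 24 with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the 24 lists. Of these, 5 passed, and the NF-kB list alone passed with an estimated correlation. The estimated setting was stricter even where members were not correlated. The interferon list had an estimated correlation of -0.013, below the preset 0.01. Its unadjusted camera p was 0.00996 at the preset and 0.0483 with the estimate. A call lost under that setting is therefore not by itself a sign of correlated members. Counts of members are given over all genes tested and adjusted over the list alone. Lists stood for RNase P, RNA polymerase III, cell cycle, stress, signalling, breast line, other cell type and RNA quality genes, and 39 list members were not analysed here, while others were listed but fell under the filter on low values and were not tested. Genes were named by a rule fixed beforehand. RPPH1 and PARP2 came first, then up to 10 genes per direction with the largest fold among those with an adjusted p under 0.05, a mean of at least 1 FPKM, a symbol that was not a clone or locus name and groups that did not overlap. Where none passed in a direction, the 5 genes with the smallest p were named as not passing. Each list gave up to 4 tested members with the smallest p, or at most 1 example where no member passed, and Y-linked genes and XIST were never named. G0S2, PI3, ICAM1, NDRG1 and the genes LAMB3, SERPINB2, ADAMTS9, PTGES, CAVIN2 and SRGAP2B were chosen after their values were seen. Of the genes the rule takes, 2 are not reported here.

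Alternatives fixed beforehand were a pseudocount of 0.1, no filter on low values, a stricter filter of at least 1 CPM of recovered fragments in at least 3 libraries, the replicate number as a block, leaving out each library, a fold of at least 2, an estimated correlation per list and fry. limma-voom on the recovered fragments and a median-of-ratios rescaling were added after seeing the data. Negative binomial count models were not used here. Gene Ontology terms in the deposited gene annotation with 15 to 500 tested members, 1829 in all, were tested with camera in the same way. No column of per-sample values was left unused. Gene coordinates came from GENCODE 29 on GRCh38, and GC content from its longest transcript per gene. Gene length was recovered from the FPKM values with the fragments, as the smallest length that fits, so a true length may be a multiple of it.

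The limma and camera steps were tested on 10 simulated data sets of the same 10909 genes, with fragments drawn from the real means and totals at a dispersion of 0.002 and 200 genes of over 200 fragments changed in each. For the comparison of RPPH1 with control libraries, 5.2% of genes changed by a factor of 1.1 were called in the right direction, 49.8% at 1.2, 91.2% at 1.3, 99.7% at 1.5 and 100% at 2. Of all genes called, 6.8% had not been changed. Every gene was drawn at the same dispersion, while the spread of real genes varies. The number of changed genes was also set, and it affects the adjusted p-values. The shares called therefore need not hold in the real comparison. A list of 24 genes shifted by 0.13 on the log2 scale had a camera p under 0.05 in 10 of 10 data sets. Genes were drawn independently, so members of this list were not correlated, while the estimated correlation of the real G2/M list was 0.361. How often camera calls an unshifted list of correlated genes was not simulated.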

Results

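Expression was measured by RNA sequencing in MDA-MB-231 cells, a human triple-negative breast cancer line with mesenchymal features, that overexpressed the noncoding RNA RPPH1 from a vector. The control cells carried the corresponding control vector. Each group had 3 libraries, and the single comparison asked which transcripts changed when RPPH1 was overexpressed. RPPH1 is the RNA subunit of RNase P, the enzyme that trims the 5' ends of precursor tRNAs. The library totals recovered from the FPKM values were 18817269, 18204469 and 18341096 fragments for control replicates 1, 2 and 3, and 18274890, 17953727 and 17603126 fragments for RPPH1 replicates 1, 2 and 3. The deepest library exceeded the shallowest by 6.9%, and the median tested gene had 835 fragments per library. The labels did not say whether replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

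Overexpression of RPPH1 was accompanied by small differences, the clearest of them lower levels of NF-kB target genes and cytokines. G2/M and mitotic genes were higher as a list by camera at a preset correlation, a call lost with an estimated correlation (adjusted p 0.386) and with fry (adjusted p 0.126). Of 10909 genes tested, 0 rose and 1 fell over all genes at an adjusted p under 0.05 by limma. MMP1, CXCL8 and G0S2 missed that threshold, each with a limma adjusted p of 0.0507. G0S2, which encodes an inhibitor of triglyceride lipase, was at 466 ± 33.5 FPKM in controls and 358 ± 2.92 FPKM in RPPH1 cells (mean ± SD, n = 3 per group, as in all values of this kind), a log2 fold change of -0.38 with an SE of 0.0478, and was chosen after its values were seen. CXCL8 on chromosome 4 (73740506 to 73743716) and MMP1 on chromosome 11 (102789920 to 102798160; GRCh38, GENCODE 29) are described with their groups.

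With limma, 869 genes had an unadjusted p under 0.05, and 545 is 5% of the genes tested. Of the 10 splits of the 6 libraries into 3 and 3, 2 reached that count, the real one included, and the highest other split had 957. The excess over 545 is therefore not particular to the real groups. Of these 869 genes, 468 had higher and 401 lower means in RPPH1 cells. No gene with an unadjusted p under 0.05 by limma had an absolute log2 fold change of 1 or more on the log2(FPKM + 1) scale. The median absolute log2 fold change of all tested genes was 0.05. For genes at low levels this scale can hide a factor of 2 in FPKM. The groups did not overlap in 1511 genes, or 13.9%, where chance gives 10% on average. Correlated genes can carry a single split away from 10%, and overlap was not counted in the other splits. limma-voom on the recovered fragments called 17 genes, 7 higher and 10 lower, among them MMP1, CXCL8 and TNFAIP3. Leaving out control replicate 1, which stood apart on the first principal component at -10.9 against -0.11 to 4.4 for the others, gave 7 genes. The count was 0 without control replicate 2, control replicate 3, RPPH1 replicate 1 or RPPH1 replicate 2.

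RPPH1 itself was not analysed here, so the overexpression has no check from its own transcript. The RPPH1 gene occupies chromosome 14 from 20343075 to 20343407 on the minus strand and is annotated as a ribozyme. PARP2, a DNA repair enzyme gene, starts 174 bases away on the plus strand (20343582 to 20357905) and is transcribed in the opposite direction. PARP2 had 24.3 ± 2.12 FPKM in controls and 24.2 ± 0.475 FPKM in RPPH1 cells, a log2 fold change of -0.0041 with an SE of 0.06 and an adjusted p of 0.991 by limma. Of 9 tested protein subunits of RNase P and RNase MRP, 4 had higher and 5 lower means, and 0 passed by limma or voom over all genes or adjusted over the list alone (camera adjusted p = 0.82). POP4 was the example with the smallest p, at 13.2 ± 0.723 FPKM against 13.95 ± 0.666 FPKM. The 28 tested genes of RNA polymerase III transcription and tRNA maturation gave 0 passing genes by either adjustment in limma or voom, with BRF2 at 4.67 ± 0.140 FPKM in controls and 4.08 ± 0.151 FPKM in RPPH1 cells and a camera adjusted p of 0.379.

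NF-kB targets and cytokines were lower as a list in RPPH1 cells. Of 21 tested members, 20 had lower means, the median log2 fold change was -0.13, and camera gave an adjusted p of 3.1e-16, or an adjusted p of 0.0291 with an estimated correlation. By limma, no member passed over all genes tested, and 11 were lower when adjusted over the list alone. By voom, CXCL8 (adjusted p 0.000889) and TNFAIP3 (adjusted p 0.0011) passed over all genes, and 12 over the list alone. CXCL8, a neutrophil-attracting chemokine, was at 393 ± 13.4 FPKM in controls and 325 ± 5.63 FPKM in RPPH1 cells (log2 fold change -0.27, limma adjusted p 0.0507). TNFAIP3, a feedback inhibitor of NF-kB signalling, was at 17.2 ± 0.210 FPKM and 13.4 ± 0.521 FPKM (log2 fold change -0.34, limma adjusted p 0.0604). The cytokine gene CSF2 was at 66.1 ± 3.72 FPKM and 53.9 ± 2.20 FPKM, and CXCL3, whose sequence is close to those of CXCL1 and CXCL2 so that its level is uncertain, at 43.4 ± 4.05 FPKM and 35.4 ± 1.69 FPKM. The mean of the list lay between -0.02 and 0.01 of the control mean in the 3 controls and between -0.20 and -0.13 in the 3 RPPH1 libraries. With no filter on low values, 8 members were lower and 1 higher over the list alone. The number of members lower over the list alone was 6 without RPPH1 replicate 1 and 7 without RPPH1 replicate 3 or control replicate 3.

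**Figure D1:**
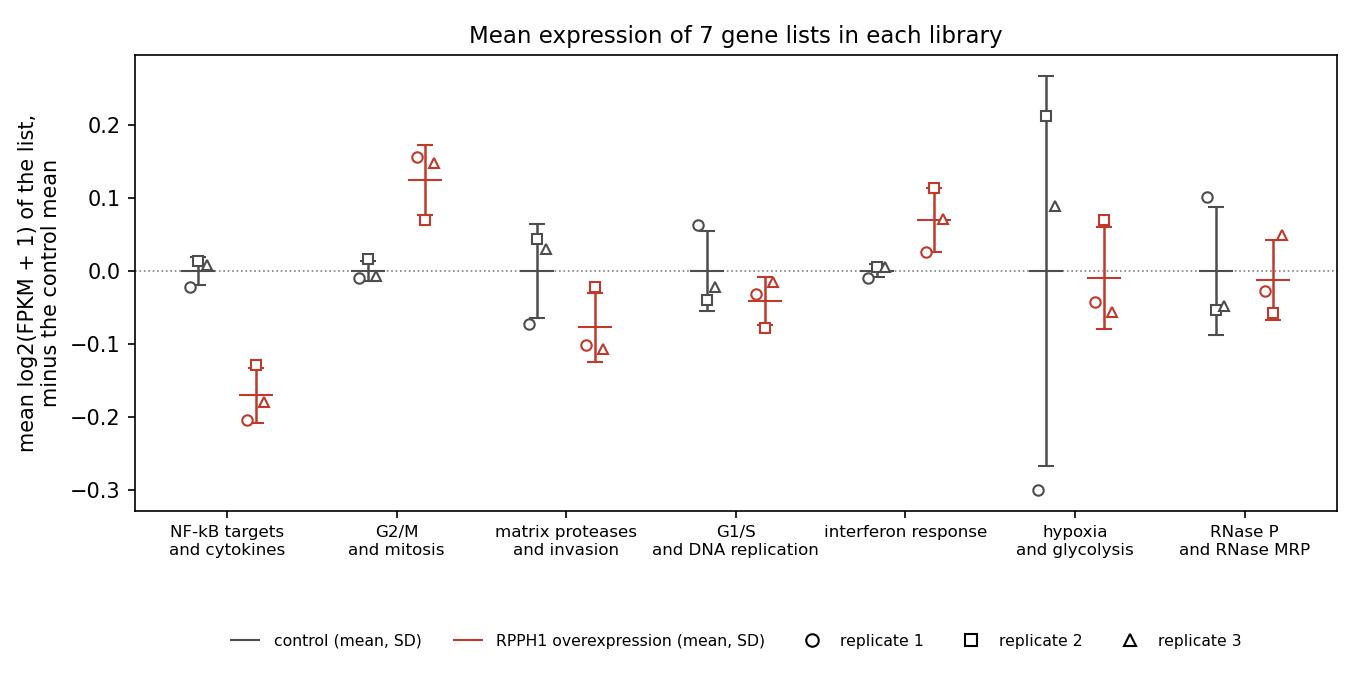
Mean log2(FPKM + 1) of 7 gene lists in each library, minus the control mean, with symbols for the 6 libraries and bars for the group mean and SD (n = 3). NF-kB targets lay at -0.20 to -0.13 and G2/M genes at 0.07 to 0.16 in the RPPH1 libraries, apart from the controls, while hypoxia and glycolysis genes ran from -0.30 to 0.21 among the controls alone.

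G2/M and mitosis genes were higher as a list. Of 24 tested members, 23 had higher means, with a median log2 fold change of 0.13 and a camera adjusted p of 8.28e-16. The call was lost with an estimated correlation (adjusted p = 0.386 with an estimated correlation). By limma, no member passed over all genes, and 16 were higher when adjusted over the list alone. This limma count was 1 without control replicate 3, 1 without RPPH1 replicate 1 and 1 without RPPH1 replicate 3. KIF20A, a kinesin of cytokinesis, was at 37.8 ± 1.40 FPKM in controls and 45.2 ± 1.40 FPKM in RPPH1 cells (log2 fold change 0.25, limma adjusted p 0.182), and passed over all genes by voom (adjusted p 0.0206). The mitotic kinase gene AURKA was at 48.4 ± 0.993 FPKM and 55.0 ± 1.83 FPKM. The mitotic cyclins CCNB1 and CCNB2 were at 105 ± 3.68 FPKM and 36.8 ± 0.878 FPKM in controls, and 118 ± 2.55 FPKM and 41.2 ± 1.59 FPKM in RPPH1 cells. Genes of G1/S and DNA replication went the other way as a list, with 20 of 26 members at lower means, a median log2 fold change of -0.04 and a camera adjusted p of 0.0292. That call was lost with an estimated correlation (adjusted p = 0.786 with an estimated correlation), without control replicate 1 (adjusted p 0.604) and without RPPH1 replicate 2 (adjusted p 0.392). The median was 0.0058 without control replicate 1, where the mean of -0.0102 stayed below 0, and -0.0145 without RPPH1 replicate 2. Library means of the G1/S list overlapped between groups, at -0.04 from the control mean in control replicate 2 and -0.01 in RPPH1 replicate 3 (exact permutation p 0.5). By limma or voom, none of the 26 passed over all genes or adjusted over the list alone (1 was lower over the list alone without control replicate 2), and E2F1, a transcription factor of S-phase entry, was the example at 26.6 ± 1.60 FPKM and 23.2 ± 0.402 FPKM.

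Matrix protease and invasion genes were lower as a list, with 15 of 18 members at lower means, a median log2 fold change of -0.06 and a camera adjusted p of 0.00808 (adjusted p = 0.687 with an estimated correlation). By limma, no member passed over all genes, while 3 were lower and 1 was higher when adjusted over the list alone; by voom, 2 were lower over all genes, MMP1 among them (adjusted p 0.000437). The collagenase gene MMP1 was at 921 ± 27.1 FPKM in controls and 768 ± 14.9 FPKM in RPPH1 cells (log2 fold change -0.26, limma adjusted p 0.0507). MMP3 was at 8.22 ± 2.04 FPKM and 5.89 ± 0.207 FPKM, and TIMP3, an inhibitor of metalloproteases, at 56.6 ± 6.69 FPKM and 67.8 ± 5.01 FPKM. Library means of this list overlapped between groups, at -0.07 from the control mean in control replicate 1 and -0.02 in RPPH1 replicate 2 (exact permutation p 0.2). The list missed the threshold without control replicate 2 (adjusted p 0.151), control replicate 3 (0.0731) or RPPH1 replicate 3 (0.0634). Its median was -0.0195 and -0.0267 without control replicates 2 and 3, and -0.0292 and -0.0341 without RPPH1 replicates 1 and 3. Over the list alone, 6 members were lower without control replicate 1, and 0 were higher without any one library other than control replicate 3.

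**Figure D2:**
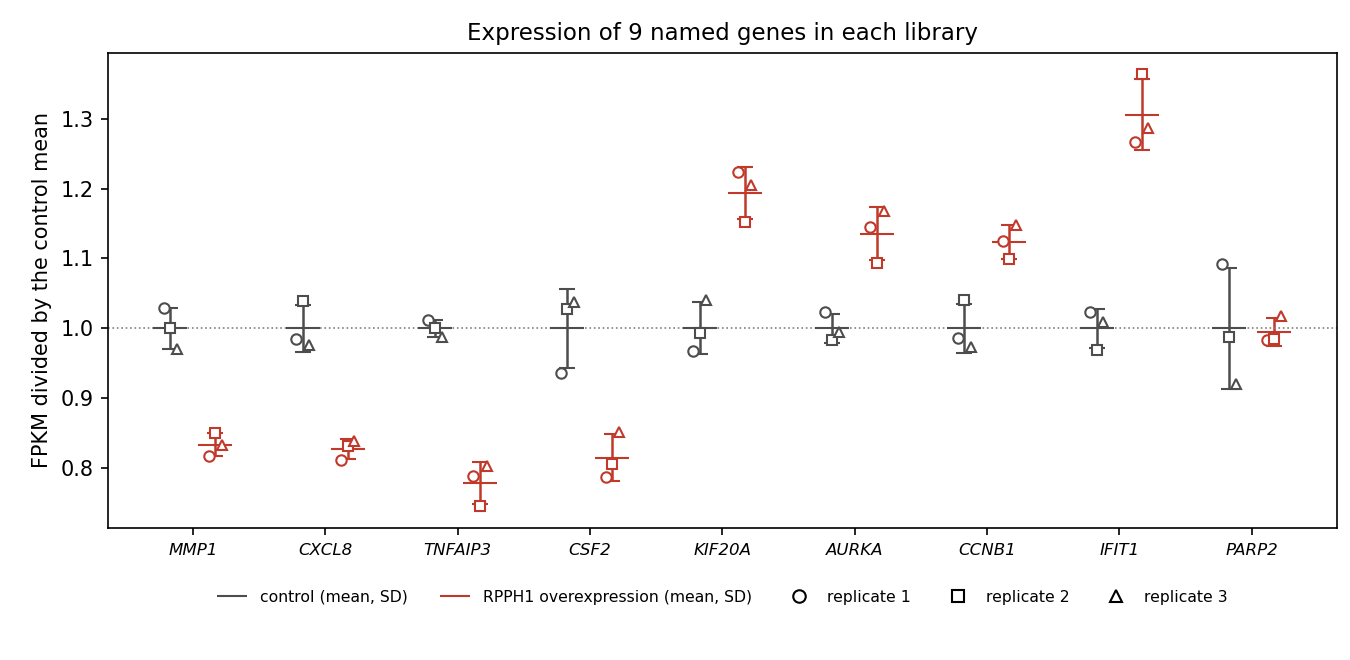
FPKM of 9 named genes in each library, divided by the control mean of the gene, with symbols for the 6 libraries and bars for the group mean and SD (n = 3). CXCL8 lay at 0.827 of the control mean in RPPH1 cells and KIF20A at 1.19, while PARP2 lay at 0.995.

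Interferon response genes were higher as a list, with 12 of 20 tested members at higher means, a median log2 fold change of 0.03 and a mean of 0.07 (camera adjusted p 0.0478, adjusted p = 0.386 with an estimated correlation). The estimated correlation was -0.013, below the preset 0.01, so correlated members do not account for that loss. By limma, no member passed over all genes, and 4 were higher when adjusted over the list alone. IFIT1, which binds RNA with a foreign 5' end, was at 7.99 ± 0.223 FPKM in controls and 10.4 ± 0.408 FPKM in RPPH1 cells (log2 fold change 0.35, limma adjusted p 0.071), and passed over all genes by voom (adjusted p 0.0138). IFIT2 was at 16.5 ± 1.42 FPKM and 20.6 ± 1.02 FPKM, IFI44 at 13.7 ± 0.700 FPKM and 15.8 ± 0.506 FPKM, and the double-stranded RNA sensor IFIH1 at 3.65 ± 0.300 FPKM and 4.49 ± 0.157 FPKM. The list missed the threshold without control replicate 1 (adjusted p 0.0589), control replicate 3 (0.0731), RPPH1 replicate 2 (0.222) or RPPH1 replicate 3 (0.0634). Its median was 0.0656 without control replicate 2, 0.084 without RPPH1 replicate 1 and 0.0028 without RPPH1 replicate 3. Over the list alone, 2 members were higher without control replicate 2, RPPH1 replicate 1 or RPPH1 replicate 2.

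The 5 genes with the smallest p among those with higher means did not pass by limma, while voom called IFIT1, KIF20A and CD55 (adjusted p 0.0138, 0.0206 and 0.0206). They were UQCRHL at 12.8 ± 0.681 FPKM and 17.0 ± 0.852 FPKM (log2 fold change 0.38), IFIT1 and KIF20A given above, RHOB at 18.1 ± 0.625 FPKM and 22.0 ± 0.823 FPKM (0.27), and the complement inhibitor CD55 at 46.1 ± 1.25 FPKM and 54.8 ± 2.35 FPKM (0.25). UQCRHL is a near-copy of UQCRH, so its level is uncertain.

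Of 15 tested p53 targets, 0 passed over all genes by limma and 1 was lower when adjusted over the list alone, and the list did not pass camera (adjusted p 0.465), with a median of 0.0006 while the mean of -0.015 and camera's direction were below 0. The cell cycle inhibitor CDKN1A was that gene, at 74.6 ± 1.69 FPKM in controls and 63.4 ± 2.01 FPKM in RPPH1 cells, and voom called it over all genes (adjusted p 0.0206). SESN1 was at 1.17 ± 0.1304 FPKM and 1.41 ± 0.118 FPKM, FDXR at 5.95 ± 0.489 FPKM and 5.39 ± 0.0774 FPKM, and GADD45A at 36.2 ± 3.85 FPKM and 33.5 ± 1.29 FPKM. Of 10 tested mesenchymal markers, 0 passed over all genes by limma and TGFB2 alone was higher when adjusted over the list alone, at 9.03 ± 0.198 FPKM and 11.3 ± 0.562 FPKM (camera adjusted p 0.825). By voom, TGFB2 passed over all genes (adjusted p 0.0206). Without control replicate 1, 2 mesenchymal markers were lower over the list alone. VIM, the intermediate filament vimentin, was at 2699 ± 38.3 FPKM and 2599 ± 21.9 FPKM, ZEB1 at 11.99 ± 0.303 FPKM and 12.8 ± 0.661 FPKM, and ITGA5 at 69.9 ± 8.80 FPKM and 64.2 ± 4.30 FPKM. None of 9 tested epithelial markers passed by either adjustment in limma or voom, with CLDN4 at 19.1 ± 2.89 FPKM and 21.4 ± 1.17 FPKM (camera adjusted p 0.465).

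Of 22 tested apoptosis regulators, 0 passed over all genes by limma or voom, and BCL2A1 was lower and PMAIP1 higher when adjusted over the list alone by limma (0 by voom; camera adjusted p 0.379). BCL2A1, an antiapoptotic relative of BCL2, was at 8.26 ± 0.873 FPKM in controls and 6.39 ± 0.597 FPKM in RPPH1 cells, and PMAIP1, which encodes the proapoptotic protein NOXA, at 39.6 ± 1.39 FPKM and 44.0 ± 0.545 FPKM. BIK was at 1.65 ± 0.276 FPKM and 2.32 ± 0.314 FPKM, and BCL2L1 at 107 ± 4.94 FPKM and 114 ± 1.06 FPKM. Over the list alone, 0 apoptosis regulators passed without control replicate 2, control replicate 3 or any one RPPH1 replicate, with median-of-ratios scaling or with no filter on low values. Of 20 cholesterol synthesis genes, 0 passed over all genes by limma or voom and INSIG1 was lower when adjusted over the list alone, at 39.7 ± 0.339 FPKM and 34.5 ± 1.65 FPKM (camera adjusted p 0.82). Over that list alone, 0 passed with the replicate number as a block and without control replicate 2, control replicate 3, RPPH1 replicate 1 or RPPH1 replicate 3, and 1 was also higher without control replicate 1. MSMO1 was at 15.7 ± 1.31 FPKM and 17.6 ± 0.520 FPKM, LSS at 13.9 ± 1.17 FPKM and 12.8 ± 0.289 FPKM, and FDFT1 at 7.54 ± 0.150 FPKM and 8.02 ± 0.377 FPKM.

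Hypoxia and glycolysis genes gave 0 passing members of 22 by either adjustment in limma or voom (camera adjusted p 0.82), with SLC2A3 at 14.3 ± 2.16 FPKM and 15.6 ± 0.852 FPKM. The mean of this list was -0.30, 0.21 and 0.09 from the control mean in control replicates 1, 2 and 3 and between -0.06 and 0.07 in the RPPH1 libraries. Without control replicate 1 the list was lower in RPPH1 cells (camera adjusted p 4.63e-12), with 6 members lower over the list alone, and without control replicate 2 it was higher (adjusted p 0.0141). Both calls are at the preset correlation, while the correlation estimated in the 6 libraries was 0.868 and gave an adjusted p of 0.941 with all of them. Oxidative phosphorylation genes did not pass (camera adjusted p 0.0689, 27 tested), with NDUFA4 at 55.3 ± 0.628 FPKM and 59.2 ± 1.98 FPKM, but did, with higher means, with no filter on low values (0.0427) and without control replicate 1 (0.0455) or RPPH1 replicate 1 (0.0354), all at the preset correlation. With all libraries, its adjusted p was 0.594 with an estimated correlation and 0.175 with fry.

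The remaining tested lists had 0 members passing by either adjustment in limma; voom had 1 higher over the list alone among heat shock genes and 1 among unfolded protein response genes. With one library left out, limma had 1 higher heat shock gene without control replicate 3, 1 higher histone gene without control replicate 2, and 1 higher and 1 lower TGF-beta and YAP target without control replicate 1, each over the list alone. Histone genes also had 1 higher and 1 lower with the replicate number as a block, and 1 lower with no filter on low values. The camera adjusted p was 0.0929 for heat shock and chaperones, 0.31 for replication-dependent histone mRNAs, 0.379 for cytosolic ribosomal proteins, 0.465 for reported targets of miR-122-5p, 0.552 for Wnt targets, 0.558 for MAPK and immediate early genes, 0.613 for unfolded protein response and ATF4 targets, and 0.753 for TGF-beta and YAP targets. Their examples with the smallest p were, in the same order, BAG3, H2AC6, RPL11, CCNG1, SP5, IER3, ATF4 and TEAD1, with log2 fold changes of 0.17, 0.26, 0.10, 0.11, 0.15, -0.13, 0.13 and 0.10. Heat shock genes passed, with higher means, without control replicate 1 (adjusted p 0.00139) or RPPH1 replicate 2 (0.0277), as did ribosomal protein genes (0.00182 and 0.0109), and histone mRNAs passed without control replicate 2 (0.0391), all at the preset correlation. With all libraries and an estimated correlation, the adjusted p was 0.786 for heat shock, 0.941 for ribosomal protein and 0.687 for histone genes. H2AC6 belongs to a multicopy histone family, so its level is uncertain. Basal B breast line markers gave a camera adjusted p of 0.82, with CAV2 at 19.8 ± 1.46 FPKM and 21.8 ± 0.851 FPKM.

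Of 10 fibroblast markers, 9 had means under 1 FPKM in both groups, and with no filter on low values the list of 10 was higher in RPPH1 cells (camera adjusted p 0.0456 at the preset correlation). COL1A1 was at 3.81 ± 0.245 FPKM in controls and 3.76 ± 0.401 FPKM in RPPH1 cells. Of 11 leukocyte markers, 9 had means under 1 FPKM in both groups. CD14 was at 2.30 ± 0.241 FPKM and 3.23 ± 0.204 FPKM, higher when adjusted over the 2 tested members alone but not over all genes (limma adjusted p 0.306), and the lysosomal protein gene CD68 at 106 ± 2.10 FPKM and 103 ± 0.942 FPKM. Luminal breast line markers, 5 of 12 of them under 1 FPKM in both groups, did not pass (camera adjusted p 0.347, and 0.0234 with higher means without control replicate 3, both at the preset correlation; 0.823 with an estimated correlation and all libraries), with GATA3 at 2.80 ± 0.450 FPKM and 3.30 ± 0.0619 FPKM. Mitochondrially encoded mRNAs and small noncoding RNAs without a poly(A) tail were not analysed here.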

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

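The voom and median-of-ratios tests were added after seeing the data. Among changed genes, 1 was called with a pseudocount of 0.1 or median-of-ratios scaling, 0 with no filter on low values (16293 tested), 0 at a fold of at least 2, 4 under the stricter filter (among them G0S2, MMP1 and CXCL8) and 17 with voom on recovered fragments. Leaving out one library gave 0 to 7 calls: 7 without control replicate 1 (among them ICAM1, CSF2, CXCL8, MMP1 and G0S2), 1 without RPPH1 replicate 3, which was PI3, and 0 without any of the other 4. Beyond genes named in the report, voom called LAMB3, SERPINB2 and ADAMTS9 lower and PTGES, CAVIN2 and SRGAP2B higher, the last uncertain since it has close paralogs. With the replicate number as a block, 0 genes were called (735 at an unadjusted p under 0.05), the same 5 lists passed, and 9 rather than 16 G2/M members over the list alone. Deviations of libraries with the same number correlated at 0.057, 0.018 and -0.104, so the numbers were not taken to pair them. Of 24 lists, the same 5 passed under the stricter filter, pseudocount, scaling and voom. With no filter, 5 of 26 passed, with oxidative phosphorylation and fibroblast markers in place of matrix proteases and interferon genes. Lists passing numbered 3 to 7 with one library left out (3 without RPPH1 replicate 3), and 1 with an estimated correlation and 1 with fry, in both the NF-kB list. Adjusted p with an estimated correlation and with fry was 0.786 and 0.762 for G1/S, 0.386 and 0.126 for G2/M, 0.687 and 0.69 for matrix proteases, and 0.386 and 0.126 for interferon genes. With no filter it was 0.0691 for matrix proteases and 0.0841 for interferon genes. With one library left out it ran from 0.00304 to 0.604 for G1/S, 1.06e-07 to 0.151 for matrix proteases, 0.00984 to 0.222 for interferon genes and 4.63e-12 to 0.957 for hypoxia genes, which turned upward without control replicate 2 (0.0141). The number of G2/M members higher over the list alone was 9 rather than 16 with median-of-ratios scaling. With one library left out, the median ran from -0.0562 to 0.0058 for G1/S (above 0 without control replicate 1), -0.0787 to -0.0195 for matrix proteases and 0.0028 to 0.084 for interferon genes, and signs turned for PARP2 (-0.0602 to 0.0591), COL1A1 (-0.0857 to 0.0246) and NDRG1 (-0.6201 to 0.1132). The cause was not tested for these changes, except that fewer libraries or more genes enter some of them. The alternatives fixed beforehand for deposited counts were not run, and RPPH1 had no value under any setting. Of genes named, BIK (25 to 44 fragments per library), PI3 (31 to 63), CD14 (61 to 93), SP5 (69 to 110) and BCL2A1 (84 to 141) had the fewest.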

Other observations

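Of 1829 Gene Ontology terms, 2 were higher in RPPH1 cells by camera and 0 lower. The terms were chromosome, centromeric region (50 genes, median log2 fold change 0.07, adjusted p 0.011) and spindle midzone (24 genes, 0.04, adjusted p 0.019). Neither passed with an estimated correlation (adjusted p = 0.999 with an estimated correlation).

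The tests of gene and list counts against other splits and of the hypoxia list were chosen after the results were seen. So was the test of G1/S genes against a higher share of cycling cells. Predictions for the other tests were written before those tests were run. They concern lists and a library picked from the main results, so they were not fixed before the data were examined. In 3 of the 10 splits of the 6 libraries at least 1 gene was called, the real split included, and the highest other split called 4. At an unadjusted p under 0.05 the real split had 869 genes and the highest other 957, and voom called 17 and 39; for both, 2 of the 10 splits reached the real count. In each case the highest other split set control replicate 1 with RPPH1 replicates 1 and 3 against the rest, which points to a structure of the samples beyond their groups. In 8 of the 10 splits at least 5 lists passed camera at the preset correlation, with 5 in the real split and 12 in the highest other. With an estimated correlation, 1 list passed in the real split and 0 in each of the others, so 1 of 10 splits reached it. With 10 splits, the share cannot fall under 0.1.

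NF-kB targets and cytokines were lower in RPPH1 cells, at a median log2 fold change of -0.13. Without control replicate 1 the median was -0.1292. The group difference in the mean of the list over libraries, a different measure from the median, then had an SE of 0.0222. Control replicate 1 had the lowest list mean of the controls, at -0.0218 from the control mean, on the side of the RPPH1 libraries. Leaving it out could only widen the difference in means. It was therefore no real test of that library as the source. After a regression of all fold changes on GC content, length and expression level, the median residual was -0.1585, which argues against those 3 properties as the whole cause. In 1 of 10 splits, the real one, the camera p was as small, with a negative log10 p of 16.9 against 4.93 for the highest other, and 10 splits are too few for a share under 0.05. An effect of RPPH1 on NF-kB signalling may be one explanation and a difference in culture density or harvest another, and neither was tested.

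G2/M and mitosis genes were higher at a median log2 fold change of 0.13 by camera at the preset correlation, a call lost with an estimated correlation (adjusted p 0.386) and with fry (adjusted p 0.126). Without control replicate 1 the median was 0.1197, and after the regression on GC content, length and expression level it was 0.1104, which argues against both as the whole cause. The group difference in the mean of the list over libraries had an SE of 0.0298 without control replicate 1. A larger share of cycling cells at every phase would raise G1/S genes as well. These had a mean change of -0.0416 (SE 0.0371), or -0.0102 (SE 0.021) without control replicate 1. Both lay below 0.05 by more than their SE, a rule and a limit set after the results were seen. That rule is loose for so few libraries. The values lean against a G1/S rise of 0.05 or more without excluding it, and leave a smaller rise open. A difference weighted to G2/M may be one explanation. In 1 of 10 splits, the real one, the camera p was as small, with a negative log10 p of 16.2 against 8.97 for the highest other, too few splits for a share under 0.05. Whether RPPH1 or the state of the cultures at harvest lies behind it was not tested.

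Hypoxia and glycolysis genes differed among the control libraries themselves. All 22 tested members were higher in control replicate 2 than in control replicate 1, with a median log2 difference of 0.51, and NDRG1, a hypoxia-induced gene chosen after its values were seen, was at 103, 285 and 211 FPKM in control replicates 1, 2 and 3. A wrong scaling of one library would move all genes alike, but the median difference of all 10909 genes was -0.0115, which argues against it. A difference in oxygen supply or cell density between culture vessels may explain the spread, and the design has no group that tests this.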
